A study of Mus musculus with 20 samples.

How the data were processed

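The series holds RNA sequencing of mouse hepatocytes (C57BL/6) from undamaged liver, from liver at 8 times after partial hepatectomy (PHx, removal of 70% of the liver), and of hepatocyte organoids (Hep-Org) cultured in Matrigel. Per the growth protocol the liver samples were freshly isolated hepatocytes. The deposited table lists 54532 genes in 20 libraries: 2 of undamaged liver, 16 of PHx liver (6, 12, 24, 48 and 72 h and 7, 14 and 21 d, with 2 per time) and 2 of Hep-Org. Every column of the table was used, and no 2 libraries were identical. The labels name replicates and do not say whether these were separate animals or cultures. The column of undamaged replicate 1, spelled differently from its sample, was matched by elimination.

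The values were FPKM deposited by the authors. Reads were aligned with HISAT2 2.0.5 to the mouse genome mm10, per the submitters' processing notes. The counting tool, the gene annotation and any filter are not given in the sources used here, nor is strandedness. Gene symbols were found for 54409 identifiers and exon lengths for 54495 in GENCODE M21 (GRCm38), which also gave positions. FPKM multiplied by the exon length of a gene fell on whole multiples of 1 step per library for 97.9% to 98.7% of low values (up to 20 reads, tolerance 0.05 reads), so read numbers could be recovered. The recovered depth was 13.7 to 41.4 M reads per library (M, 1000000) and was 0.478 to 1.94 times the library size implied by the step. The FPKM values were therefore taken as scaled between libraries by the authors, by a method that is not stated. FPKM summed to 167676 to 988797 per library. Genes near the filter threshold rest on small read numbers.

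Genes with FPKM of at least 1 in at least 2 libraries were tested (13162 genes), on log2(FPKM + 1). The model was fitted with limma 3.58.1 in R 4.3.3 to all 20 libraries at once, with 1 mean per group and a term for submission, and with moderated variances (trend and robust options, 9 residual and 3.29 prior degrees of freedom). The series text says that a second submission extended the first, so replicate 2 of each PHx time was taken as the second submission (8 libraries) and all others as the first (12 libraries). The undamaged and Hep-Org libraries all belong to the first. The numbering of replicates was checked as a pairing: over 28 pairs of times, the correlation between the replicate differences of 2 times ran from -0.381 to 0.472 with a median of -0.115, and was over 0.1 in 4 pairs. Each PHx time and Hep-Org were compared with undamaged liver, and Hep-Org with the mean of 24 to 72 h and of 7 to 21 d. Differences over the 8 times were tested with the moderated F test. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1 (for the time course, a range of fitted means of at least 1).

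Gene lists were written before the data were examined: 35 lists with 670 entries, of which 667 were in the table. Those with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. For each list the members called over all genes are given, and those called when p-values were adjusted over the list alone. Similarity was Spearman's rho between libraries across the tested genes. Overlaps were set beside the number expected of independent sets, and the correlation of differences beside 20 simulated draws of unchanged groups against the same undamaged libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 read the table and wrote summaries.

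Named genes followed a fixed rule. For each PHx time these were the 3 called genes with the largest increase and the 3 with the largest decrease, and for Hep-Org versus undamaged liver the 10 largest each way. For the time course they were the 2 genes with the largest F at each peak time, and for Hep-Org versus each window the 3 largest each way. A gene needed a mean FPKM of at least 5 in the higher group and, outside the time course, libraries that did not overlap between groups, and predicted genes, clones and pseudogenes were left out. From each list described, up to 3 members with the largest absolute t were taken among those with a mean FPKM of at least 1. Xist, the Y-linked genes, Saa1, Clec4f and the genes given per library among the other observations were chosen after their values were seen.

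The procedure was tested on simulated data with the same groups. Of 500 genes changed by log2 1.5, 55.2% were recovered for Hep-Org and 53.8% for 72 h, and of 500 changed by log2 3, 92.6% and 91.6% (5 draws). In these draws 9.6 and 8.2 unchanged genes were called per draw, 6.10% and 5.34% of the calls and so above the 5% set. With no changed gene at most 0.35 genes were called per draw and comparison (20 draws). In the real libraries lists moved together, so these rates need not hold.

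The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, rescaling to a sum of 1000000, median-ratio rescaling, no replicate block, a replicate block by number, the first submission only, leaving out each library in turn, the undamaged and Hep-Org libraries alone, the PHx libraries alone and an estimated inter-gene correlation. Those chosen after seeing the data were limma's voom on recovered reads, 21 d or 7 d as the reference and leaving out the times of 48 h, 72 h and 7 d. No group had 3 or more libraries, so no other division of libraries was tested. Raw reads were not examined, so splicing, variants and reads shared between gene copies were left out, and mesothelial markers (4 measured) were described without a test.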

Results

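Transcript levels were measured by RNA sequencing in 20 mouse libraries. Undamaged liver was sampled in 2 libraries, regenerating liver at 8 times after partial hepatectomy (PHx, surgical removal of 70% of the liver) with 2 libraries per time, and hepatocyte organoids (Hep-Org, 3-dimensional cultures grown from hepatocytes and passaged) in 2 libraries. The times were 6, 12, 24, 48 and 72 h and 7, 14 and 21 d. Per the growth protocol the liver samples, called liver below, were freshly isolated hepatocytes of unstated purity. Differences in markers of other liver cells may reflect that purity. Values were FPKM, and the depth recovered from them was 13.7 to 41.4 M reads per library (M, 1000000). Differences are log2 differences of FPKM + 1 with their standard error (SE), and levels are mean ± SD FPKM with n = 2 in every group. Adjusted p-values are Benjamini-Hochberg values from limma for genes and from limma's camera test for gene lists. The labels do not say that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Positions are on GRCm38/mm10. The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined, while voom, the 7 d and 21 d references and the genes Xist, Ddx3y, Saa1 and Clec4f were chosen after.

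Several libraries stood apart in ways that the groups did not explain. Xist, the noncoding RNA of the inactive X chromosome, was at 13.6 to 23.7 FPKM in the 6 libraries of 48 h, 72 h and 7 d and at most at 0.137 in the other 10 PHx libraries, while the Y-linked Ddx3y was listed at 0 in those 6 and was at least at 9.66 in the other 10. Ddx3y was at 9.90 in Hep-Org replicate 1 and 0.00756 in replicate 2, with Xist at 0.00128 and 25.3. The acute-phase gene Saa1 was at 19.9 in undamaged replicate 1 and 20927 in replicate 2, and the Kupffer cell gene Clec4f at 9.16 and 183. Mitochondrial transcripts took 40.7% of the reads of 6 h replicate 2 and 3.17% to 25.1% of the reads of the others. When each library was rescaled to the same sum, the median of all genes moved to 0.08 (6 h), 0.25 (12 h), 0.20 (24 h), 0.12 (48 h), 0.55 (72 h), 0.56 (7 d), 0.49 (14 d) and 0.41 (21 d) against undamaged liver. For Hep-Org it moved to 1.54 against undamaged liver, 1.26 against 24 to 72 h and 1.05 against 7 to 21 d. Of the 188 list comparisons past the camera threshold, 20 had a median that turned sign after this rescaling. Relative to the shift of all genes 0 turned. Rescaling moves nearly all genes alike, so that outcome was largely fixed beforehand and is no separate support.

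**Figure D1:**
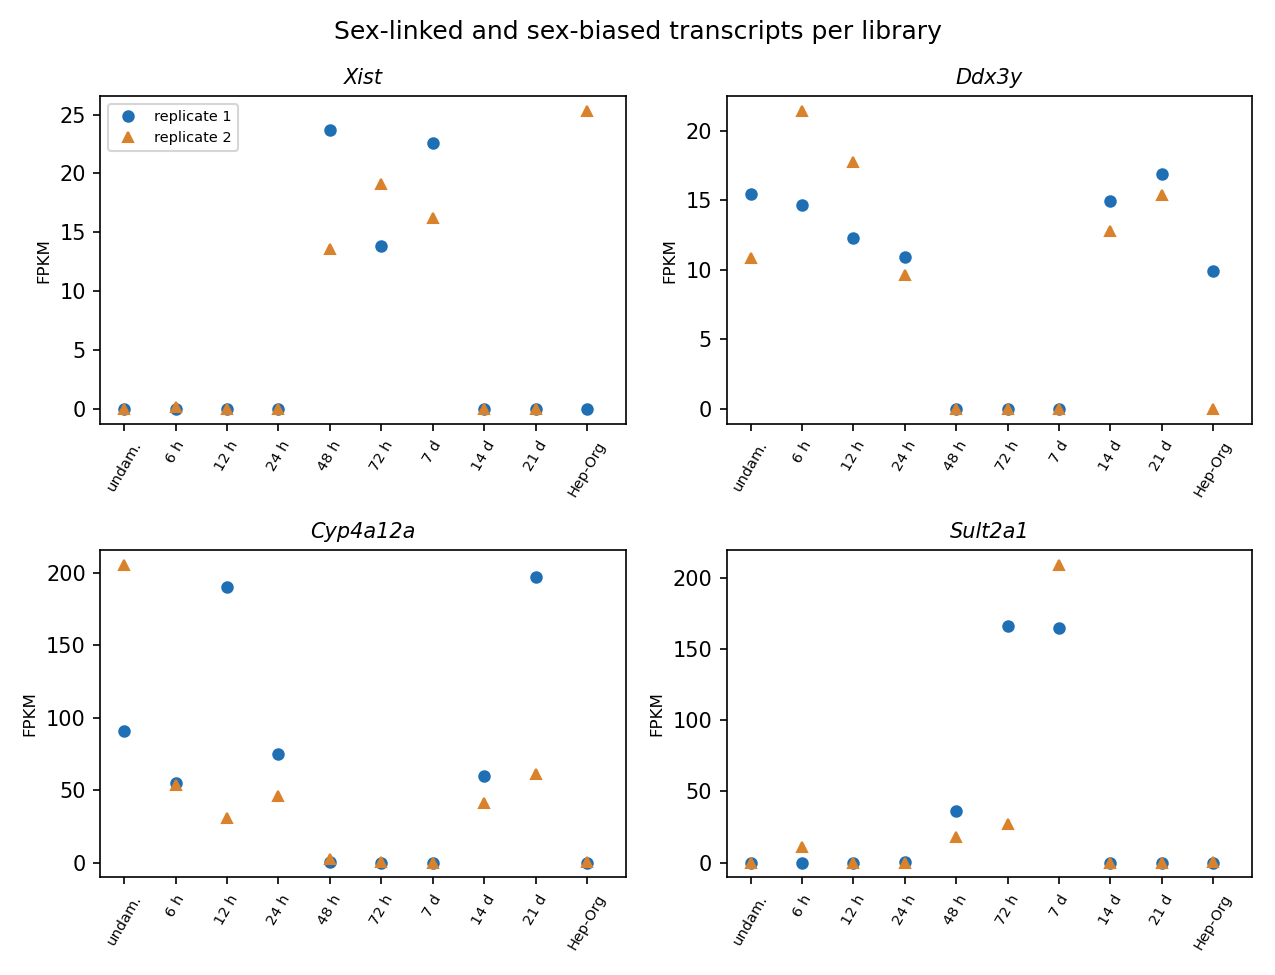
FPKM of sex-linked and sex-biased transcripts in each of the 20 libraries, with groups along the horizontal axis and circles and triangles for replicates 1 and 2. Xist lay between 13.6 and 23.7 FPKM in the libraries of 48 h, 72 h and 7 d, where Ddx3y was listed at 0.

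The first question was how liver expression changed in regeneration. A peak is the highest fitted mean, not always a rise. Transcripts with a peak at 6 h included Plk3 (ENSMUSG00000028680, chromosome 4, 117128655 to 117133963), a stress-responsive polo-like kinase, at 126 ± 14.6 FPKM at 6 h and 4.33 ± 0.543 at 21 d. Cidec (ENSMUSG00000030278), a lipid droplet protein, peaked at 12 h at 100 ± 52.8 and was at 0.551 ± 0.380 at 7 d. Cyp2r1 fell to 1.04 ± 0.721 at 6 h and was at 10.4 ± 3.67 at 14 d (undamaged 9.28 ± 2.36). Genes with a peak at 48 h, 72 h or 7 d included transcripts of the female liver: Sult3a2 at 20.7 ± 4.66 at 48 h, the organic anion transporter Slc22a27 at 20.2 ± 2.24 at 72 h and Cyp3a41a at 117 ± 39.4 at 7 d, and these libraries had the Xist pattern given above. Mup7 and Cyp4a12a, male-biased transcripts, had their highest fitted means on the log2 scale at 14 d and 21 d, with Mup7 at 8804 ± 919 FPKM at 14 d and 8902 ± 6079 at 21 d. Across the 8 times, 1252 of 13162 genes differed by limma's moderated F test (adjusted p under 0.05 and a range of fitted means of at least 1 on log2). Of these 549 peaked at 6 h, 139 at 12 h, 45 at 24 h, 39 at 48 h, 87 at 72 h, 108 at 7 d, 64 at 14 d and 221 at 21 d. The named genes had F from 12.4 for Mir7678, which peaked at 24 h at 5.40 ± 2.19, to 335 for Cyp3a41a (limma adjusted p = 0.00634 and 6.37e-09). Others were Cntrl at 6 h (F = 34.9), Kctd15 at 12 h (28.6), Cyp3a44 at 72 h (40.2) and Cyp3a41b at 7 d (286). Ormdl1 at 24 h (F = 13.7), Enpp3 at 48 h (24.5) and Lrrc3 at 21 d (42.5) lay below undamaged liver. Of the lists, cholesterol synthesis and uptake had 16 of 24 members called over time (20 adjusted over the list alone), ribosome biogenesis 9 of 23 (13 adjusted over the list alone), and the female-biased list 10 of 10. The 2 cell-cycle lists had their highest mean at 72 h, with 2 of 31 and 0 of 35 members called. Without 6 h replicate 1 the PHx time course called 741 genes and without 21 d replicate 1 it called 783. Levels of near-identical copies (such as Cyp3a41a and Cyp3a41b, the Mup genes) are uncertain, as their reads could be split.

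**Figure D2:**
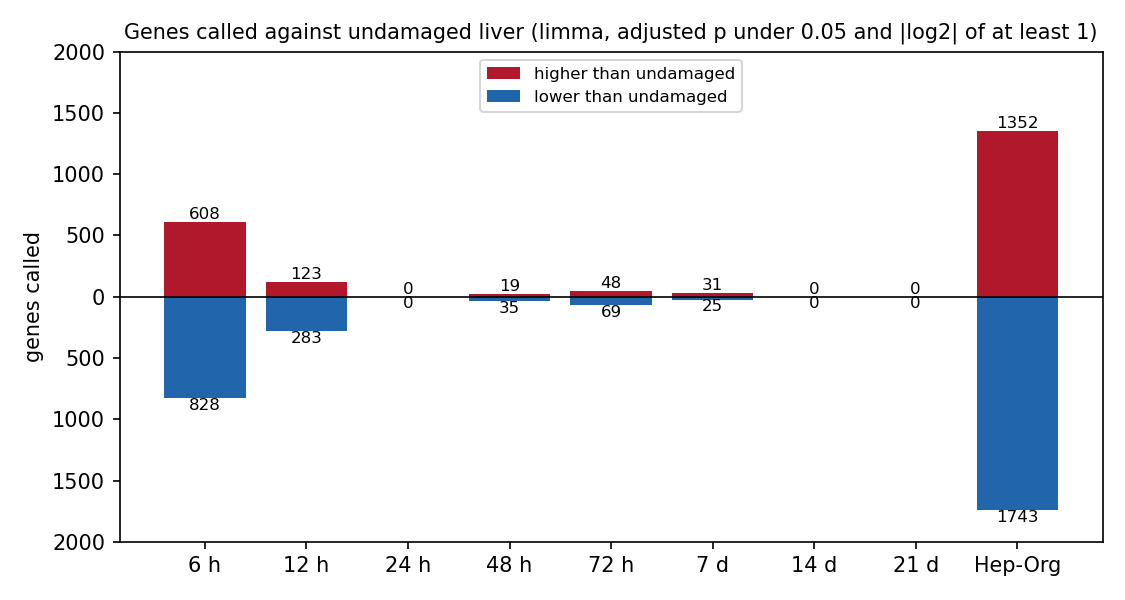
Number of genes called higher (up) or lower (down) than in undamaged liver at each PHx time and in Hep-Org, by limma at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The count was 1436 at 6 h, 0 at 24 h, 117 at 72 h and 3095 in Hep-Org.

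At 6 h after PHx, immediate-early genes were higher and genes of cholesterol synthesis, bile acid transport and drug metabolism were lower than in undamaged liver. The transcription factor Myc (chromosome 15, 61985391 to 61990374) rose from 1.45 ± 0.000188 to 8.23 ± 1.28 FPKM (log2 1.93, SE 0.266, limma adjusted p = 0.00196) and Ier3 (chromosome 17, 35821684 to 35822923), an early stress response gene, from 0.371 ± 0.280 to 25.3 ± 19 (log2 4.11, SE 0.575, limma adjusted p = 0.00201). Squalene synthase, Fdft1 (chromosome 14, 63145150 to 63179578), fell from 51.4 ± 14.0 to 2.25 ± 1.31 (log2 -4.02, SE 0.502, limma adjusted p = 0.00139), with Sc5d, a late enzyme of the pathway, at log2 -4.00. The largest decreases were in Hsd3b5, a male-biased steroid dehydrogenase (chromosome 3, 98618634 to 98630252), from 154 ± 66.9 to 0.785 ± 0.155 (log2 -6.40, SE 0.843, limma adjusted p = 0.00156), the water channel Aqp8 (log2 -4.67) and Mup4, which was listed at 0 in both 6 h libraries and at 25.5 ± 1.17 in undamaged liver. The largest increases were in globin genes, Hba-a1 (ENSMUSG00000069919, log2 8.87, SE 1.77, limma adjusted p = 0.00940), Hbb-bs (8.29) and Hba-a2 (6.81), red blood cell transcripts that differed widely between the replicates (Hbb-bs at 3059 and 140 FPKM). Under PHx 6 h versus undamaged, limma called 608 genes higher and 828 lower of 13162, after rescaling to the same sum 158 and 265, and without 6 h replicate 1 it called 474 in all. Leaving out undamaged replicate 1 or 6 h replicate 1 ended the calls of Hba-a1 (log2 7.04 to 7.40) and Hbb-bs (5.84 to 7.08), 3 libraries each ended those of Hba-a2 (4.97 to 6.85) and Aqp8 (-4.68 to -4.51), and 2 that of Mup4.

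Among the fixed lists at 6 h, cholesterol synthesis and uptake fell most clearly: 21 of 24 measured members were lower and none higher, all 24 were lower adjusted over the list alone, and the median was -2.95 (camera adjusted p = 3.73e-18, 0.406 at an estimated correlation). Of 22 immediate-early genes 6 were higher, 8 adjusted over the list alone (median 1.29, camera adjusted p = 8.82e-06, 0.406 at an estimated correlation). Fosl2 of the AP-1 family was at 5.54 ± 2.52 against 1.07 ± 0.777. Ribosome biogenesis factors rose, 9 of 23 called and 10 adjusted over the list alone (median 0.87, camera adjusted p = 2.69e-08, 0.406 at an estimated correlation). The nucleolar proteins Nop2 (log2 1.89), Mybbp1a (1.56) and Nop58 (1.39) were among them. Cytochrome P450 and drug metabolism genes fell, 10 of 32 lower and 1 higher (14 and 2 adjusted over the list alone, median -1.64, camera adjusted p = 8.40e-05, 0.409 at an estimated correlation). Cyp2f2 was at 115 ± 69.9 against 906 ± 135. Bile acid genes fell, 5 of 22 lower and 8 adjusted over the list alone (median -1.65, camera adjusted p = 4.83e-04, 0.406 at an estimated correlation). The uptake carriers Slco1b2 and Slc10a1 were at log2 -3.35 and -2.91. Lipogenesis fell, 6 of 16 lower and 7 adjusted over the list alone (median -0.98, camera adjusted p = 8.12e-05, 0.406 at an estimated correlation). ATP citrate lyase, Acly, was at 5.83 ± 1.69 against 50.2 ± 23.2. Hepatocyte identity genes fell, 5 of 30 lower and 7 adjusted over the list alone (median -1.31, camera adjusted p = 6.33e-04, 0.409 at an estimated correlation). Periportal genes also fell (5 of 16 lower, 8 adjusted over the list alone, median -1.63, camera adjusted p = 0.00124, 0.409 at an estimated correlation). Of the acute-phase list Socs3, a feedback inhibitor of cytokine signalling, was higher (77.1 ± 25.1 against 8.94 ± 9.61) and Crp lower (59.4 ± 18.4 against 723 ± 787), and the list did not pass the test (median 0.34, camera adjusted p = 0.634). Its direction depended on the undamaged library, with a median of -1.75 without undamaged replicate 1 (camera adjusted p = 0.00126) and 2.38 without undamaged replicate 2 (camera adjusted p = 5.12e-05). Against 21 d, a reference chosen after the data were seen, it was 2.16, with 4 of 27 higher, 4 adjusted over the list alone (camera adjusted p = 0.00136, 0.641 at an estimated correlation).

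Transcripts of other cell types moved with these groups at 6 h. Of 17 stellate and mesenchymal markers 4 were higher, 7 adjusted over the list alone (median 0.88, camera adjusted p = 3.24e-05, 0.406 at an estimated correlation). Of 6 erythroid markers 4 were higher (4 adjusted over the list alone, median 6.51, camera adjusted p = 0.0191, 0.409 at an estimated correlation). Of 7 lymphocyte markers 2 were higher, 6 adjusted over the list alone (median 1.47, camera adjusted p = 0.00178, 0.409 at an estimated correlation). Neutrophil markers had 0 of 11 called, 4 adjusted over the list alone (median 2.18, camera adjusted p = 0.0109, 0.637 at an estimated correlation). Mitochondrially encoded mRNAs had 0 of 13 called, 0 adjusted over the list alone (median 1.38, camera adjusted p = 0.0346, 0.725 at an estimated correlation). Endothelial markers had 0 of 15 called, 0 adjusted over the list alone (median 0.52, camera adjusted p = 0.0486, 0.726 at an estimated correlation), a call that ended without any 1 of 6 libraries (-0.16 to 0.50). Without 6 h replicate 1 the list calls ended for hepatocyte identity (median -0.63), periportal genes (-0.82), lymphocytes (0.60), neutrophils (0.92) and erythroid markers (4.79). Without undamaged replicate 1 they ended for neutrophils (1.13) and mitochondrial mRNAs (0.73), without undamaged replicate 2 for erythroid markers (6.68), and without 6 h replicate 2 for mitochondrial mRNAs (0.51).

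At 12 h, Cidec and the fatty acid hydroxylase Cyp4a14 were the largest increases beside globin, and cholesterol synthesis and lipogenesis were lower. Cidec (chromosome 6, 113424634 to 113435760) rose from 0.939 ± 0.213 to 100 ± 52.8 FPKM (log2 5.53, SE 0.540, limma adjusted p = 0.00112) and Cyp4a14, a PPARA target, from 2.32 ± 1.98 to 371 ± 295 (log2 6.82, SE 1.48, limma adjusted p = 0.0309). Srebf1, a transcription factor of lipid synthesis, fell from 50.0 ± 18.1 to 5.39 ± 1.21 (log2 -2.95, SE 0.594, limma adjusted p = 0.0220). Hsd3b5, Aqp8 and Mup4 were again the largest decreases (log2 -6.92, -4.84 and -4.61), and Hba-a1 was higher (7.59). Of 24 cholesterol genes 15 were lower, 23 adjusted over the list alone (median -2.74, camera adjusted p = 5.36e-21, 0.218 at an estimated correlation). Of 16 lipogenesis genes 4 were lower, 8 adjusted over the list alone (median -1.80, camera adjusted p = 1.77e-07, 0.218 at an estimated correlation). Bile acid genes had 4 of 22 lower, 6 adjusted over the list alone (median -1.49, camera adjusted p = 9.55e-05, 0.459 at an estimated correlation). The bile salt export pump Abcb11 was at 13.2 ± 10.1 against 176 ± 24.2. P450 genes had 5 of 32 lower and 1 higher, 12 and 2 adjusted over the list alone (median -1.43, camera adjusted p = 1.15e-04, 0.537 at an estimated correlation). Growth factors and receptors fell, with 3 of 19 lower, 7 adjusted over the list alone (median -0.47, camera adjusted p = 0.00802, 0.364 at an estimated correlation). The 3 were the receptors Lifr (log2 -2.54), Ghr (-2.10) and Fgfr4 (-1.71). Ribosome biogenesis factors were higher as a list with 0 of 23 called, 2 adjusted over the list alone (median 0.60, camera adjusted p = 2.56e-05, 0.537 at an estimated correlation). Of 6 erythroid markers 1 was higher, 4 adjusted over the list alone (median 5.64, camera adjusted p = 0.0153, 0.537 at an estimated correlation). Stellate markers rose with 0 of 17 called, 0 adjusted over the list alone (median 0.41, camera adjusted p = 0.00278, 0.552 at an estimated correlation), and 0.16 without undamaged replicate 1, where the call ended. Of the 406 genes called, 123 were higher and 283 lower, and 91 and 262 of them were also called in that direction at 6 h (5.68 and 17.8 for independent sets, with part of the excess open to the shared undamaged libraries). With no replicate block PHx 12 h versus undamaged called 225 higher and 507 lower, and after rescaling to the same sum it called 37 and 42. It called 95 genes without 12 h replicate 1, 244 without 12 h replicate 2, 270 without 72 h replicate 1 and 270 without Hep-Org replicate 2. The calls of Cyp4a14 (log2 5.82 to 7.59), Aqp8 (-5.60 to -3.85), Hba-a1 (4.46 to 7.65) and Mup4 (-5.31 to -4.06) each ended without any 1 of 4, 8, 10 and 18 libraries, the P450 call ended without 12 h replicate 1 (-0.67), the call of growth factors and receptors without undamaged replicate 2 (-0.09) or 12 h replicate 1 (-0.35), and the erythroid call without undamaged replicate 2 (5.82) or 12 h replicate 1 (2.66).

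At 24 h no single gene passed the test, and the lists showed lower lipogenesis and cholesterol synthesis with higher DNA replication genes. Acetyl-CoA carboxylase 2, Acacb, was at 1.99 ± 0.887 FPKM against 13.8 ± 4.46 (log2 -2.30, SE 0.368, limma adjusted p = 0.0747) and Thrsp, an inducer of lipogenesis, at 10.3 ± 1.51 against 101 ± 46.8. The lipogenesis list fell with 0 of 16 members called, 6 lower adjusted over the list alone (median -1.37, camera adjusted p = 3.02e-08, 0.312 at an estimated correlation). Cholesterol synthesis fell with 0 of 24 called, 6 adjusted over the list alone (median -0.96, camera adjusted p = 1.76e-08, 0.548 at an estimated correlation). Replication genes rose as a list: 28 of 31 had a positive difference, 0 were called, 0 adjusted over the list alone (median 0.67, camera adjusted p = 2.20e-07, 0.640 at an estimated correlation). Gins1 of the replicative helicase was at 4.81 ± 2.32 against 1.59 ± 0.154 and the licensing factor Cdt1 at 2.32 ± 1.43 against 0.652 ± 0.527. Fatty acid oxidation genes rose as a list with 0 of 24 called, 0 adjusted over the list alone (median 0.79, camera adjusted p = 1.44e-04, 0.739 at an estimated correlation). Stellate markers rose with 0 of 17 called, 1 adjusted over the list alone (median 0.67, camera adjusted p = 4.48e-07, 0.427 at an estimated correlation). Against 21 d the fatty acid oxidation and stellate lists did not pass the test (medians -0.08 and 0.02, camera adjusted p = 0.824 and 0.482), and the stellate mean was 0.60 in undamaged replicate 1 and at least 1.47 in every other liver library. Male-biased genes fell with 0 of 12 called, 1 adjusted over the list alone (median -0.74, camera adjusted p = 0.00296, 0.427 at an estimated correlation), in libraries without the Xist pattern. Limma called 0 of 13162 genes, with 1380 at an unadjusted p under 0.05, and voom on recovered reads also called 0. PHx 24 h versus undamaged called 30 genes with no replicate block, 3 without undamaged replicate 1, 2 without undamaged replicate 2, 4 and 10 without 6 h replicates 1 and 2, and 23 without 24 h replicate 2. The replication list lost its call without 24 h replicate 1 (median 0.10), and fatty acid oxidation without undamaged replicate 2 (0.28) or 24 h replicate 2 (0.56).

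At 48 h, female-biased transcripts were higher and male-biased ones lower than in undamaged liver, in libraries that carried the Xist pattern, and cell-cycle lists were higher. Cyp2a4, a female-biased steroid hydroxylase, rose from 0.0809 ± 0.0351 to 83.7 ± 25.9 FPKM (log2 6.41, SE 0.874, limma adjusted p = 0.00961) and Cyp2b9 from 1.47 ± 2.08 to 130 ± 48.8 (log2 6.14). Cyp3a41a and Cyp3a41b, listed at 0 in undamaged liver, were at 35.9 ± 2.51 and 58.7 ± 11 (limma adjusted p = 4.99e-07 for both). Mup7 (ENSMUSG00000073842, chromosome 4, 60066469 to 60070475), a male-biased urinary protein, fell from 15494 ± 6962 to 13.3 ± 18.2 (log2 -11.17, SE 1.34, limma adjusted p = 0.00326), with Mup12 at log2 -9.86 and the elongase Elovl3 at -8.60. Of 10 female-biased genes 6 were higher, 10 adjusted over the list alone (median 4.98, camera adjusted p = 6.86e-29, 3.00e-04 at an estimated correlation). Of 12 male-biased genes 6 were lower, 12 adjusted over the list alone (median -4.15, camera adjusted p = 5.98e-23, 6.75e-04 at an estimated correlation). Mitotic genes were positive in 35 of 35, with 0 called and 0 adjusted over the list alone (median 0.99, camera adjusted p = 1.13e-10, 0.523 at an estimated correlation). The spindle checkpoint kinase Bub1 was at 5.92 and 1.09 in the 48 h libraries and at 0.0112 and 0.0844 in undamaged liver. Replication genes were positive in 30 of 31, with 0 called and 0 adjusted over the list alone (median 0.70, camera adjusted p = 4.19e-11, 0.366 at an estimated correlation). Acute-phase genes were positive in 24 of 27, with 0 called and 0 adjusted over the list alone (median 1.35, camera adjusted p = 5.81e-05, 0.670 at an estimated correlation). Lipogenesis fell with Acacb called of 16 and 4 adjusted over the list alone (median -0.97, camera adjusted p = 1.03e-07, 0.147 at an estimated correlation). Cholesterol synthesis fell with 0 of 24 called, 0 adjusted over the list alone (median -0.88, camera adjusted p = 2.92e-07, 0.385 at an estimated correlation). P450 genes fell with 2 of 32 lower, 1 higher and 8 lower adjusted over the list alone (median -1.0, camera adjusted p = 2.29e-05, 0.377 at an estimated correlation). Stellate markers rose with 0 of 17 called and 7 adjusted over the list alone (median 0.79, camera adjusted p = 1.70e-10, 0.185 at an estimated correlation). Kupffer cell markers rose with 0 of 15 called, 0 adjusted over the list alone (median 0.93, camera adjusted p = 0.00372, 0.682 at an estimated correlation). Endothelial (median 0.58, camera adjusted p = 0.00192, 0.682 at an estimated correlation) and neutrophil markers (0.53, camera adjusted p = 0.0378, 0.742 at an estimated correlation) also rose with 0 called, 0 adjusted over the list alone. The endothelial call ended without undamaged replicate 1 (-0.39) or 48 h replicate 1 (0.16), and the neutrophil call without any 1 of 8 libraries (-0.27 to 0.49). Limma called 19 genes higher and 35 lower, voom 7 and 5. PHx 48 h versus undamaged called 30 and 61 with no replicate block and 13 and 14 after rescaling to the same sum. It called 22 genes without undamaged replicate 1, 33 and 19 without 48 h replicates 1 and 2, and 35 without either 72 h library, and 1 gene when the 7 d libraries were the reference. Against 7 d mitotic genes did not pass the test (median 0.18, camera adjusted p = 0.0922). The mitotic call ended without 48 h replicate 1 (median -0.24) and the acute-phase and Kupffer medians turned negative without undamaged replicate 1 (-0.61 and -0.78). Without 1 library the calls ended of Cyp2a4 (2 libraries, log2 6.20 to 6.38), Cyp2b9 (3, 5.15 to 6.39), Elovl3 (10, -9.35 to -8.03) and Mup12 (15, -10.27 to -6.79).

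At 72 h the cell-cycle lists were at their highest, cholesterol synthesis was lower, and the sex-biased genes kept the pattern of 48 h. Mitotic genes rose as a list, with 0 of 35 called over all genes and 31 higher adjusted over the list alone (median 1.93, camera adjusted p = 5.38e-20, 0.321 at an estimated correlation). Bub1 (chromosome 2, 127801122 to 127831865) was at 5.70 ± 0.816 FPKM against 0.0478 ± 0.0518 (log2 2.66, SE 0.647, limma adjusted p = 0.0713) and cyclin B2, Ccnb2, at 21.2 ± 4.83 against 0.897 ± 0.683 (log2 3.48, limma adjusted p = 0.0971). Replication genes rose as a list, with 0 of 31 called over all genes, and 13 higher and 1 lower adjusted over the list alone (median 0.91, camera adjusted p = 2.21e-13, 0.287 at an estimated correlation). The sliding clamp Pcna was at 26.9 ± 8.87 against 6.98 ± 0.448. Cholesterol synthesis fell with 0 of 24 called and 15 adjusted over the list alone (median -1.48, camera adjusted p = 9.21e-10, 0.321 at an estimated correlation). Stellate markers rose with 2 of 17 called and 7 adjusted over the list alone (median 0.73, camera adjusted p = 1.19e-09, 0.230 at an estimated correlation). The matrix proteoglycan Lum (chromosome 10, 97565128 to 97572703) rose from 0.803 ± 0.882 to 9.19 ± 2.21 (log2 2.57, SE 0.416, limma adjusted p = 0.0166). Hepatocyte identity genes fell with 0 of 30 called, 0 adjusted over the list alone (median -1.02, camera adjusted p = 4.12e-05, 0.372 at an estimated correlation). Kupffer cell (median 1.27, camera adjusted p = 0.00304, 0.670 at an estimated correlation) and endothelial markers (0.58, camera adjusted p = 0.0178, 0.726 at an estimated correlation) rose with 0 of 15 called in each, 0 adjusted over the list alone. Their medians were -0.46 and -0.42 without undamaged replicate 1, which ended both calls, as did leaving out 72 h replicate 1 for Kupffer cells (0.88) and 72 h replicate 2 for endothelium (0.52). P450 genes fell with 2 of 32 lower, and 6 lower and 1 higher adjusted over the list alone (median -0.66, camera adjusted p = 0.0369, 0.670 at an estimated correlation). This median was 0.14 after rescaling to the same sum. Sult2a2, a bile acid and steroid sulfotransferase, rose from 0.0329 ± 0.0465 to 415 ± 370 (log2 8.24, SE 0.948, limma adjusted p = 0.00202), with Cyp2a4 and Cyp2b9 at log2 7.03 and 6.86. Mup7, Mup12 and Elovl3 were the largest decreases (-11.35, -10.61 and -8.10). Of 10 female-biased genes 8 were higher, 10 adjusted over the list alone (median 6.16, camera adjusted p = 2.99e-22, 8.70e-04 at an estimated correlation). Of 12 male-biased genes 9 were lower, 12 adjusted over the list alone (median -4.16, camera adjusted p = 1.87e-15, 0.00329 at an estimated correlation). Limma called 48 genes higher and 69 lower, voom 17 and 22. PHx 72 h versus undamaged called 152 and 273 with no replicate block and 92 and 14 after rescaling to the same sum. It called 283 genes without undamaged replicate 1, 23 and 17 without 72 h replicates 1 and 2, 234 and 231 without 7 d replicates 1 and 2, 71 without any 1 library of 14 d or 21 d, 66 without either Hep-Org library, and 1 when the 7 d libraries were the reference. Against 7 d, mitotic genes were also higher (median 1.17, camera adjusted p = 1.89e-23, 0.361 at an estimated correlation). Without 1 library the calls ended of Cyp2b9 (2 libraries, log2 6.84 to 6.89), Elovl3 (10, -8.96 to -7.43), Mup12 (3, -11.20 to -9.84) and the P450 list (4, median -0.67 to -0.08).

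**Figure D3:**
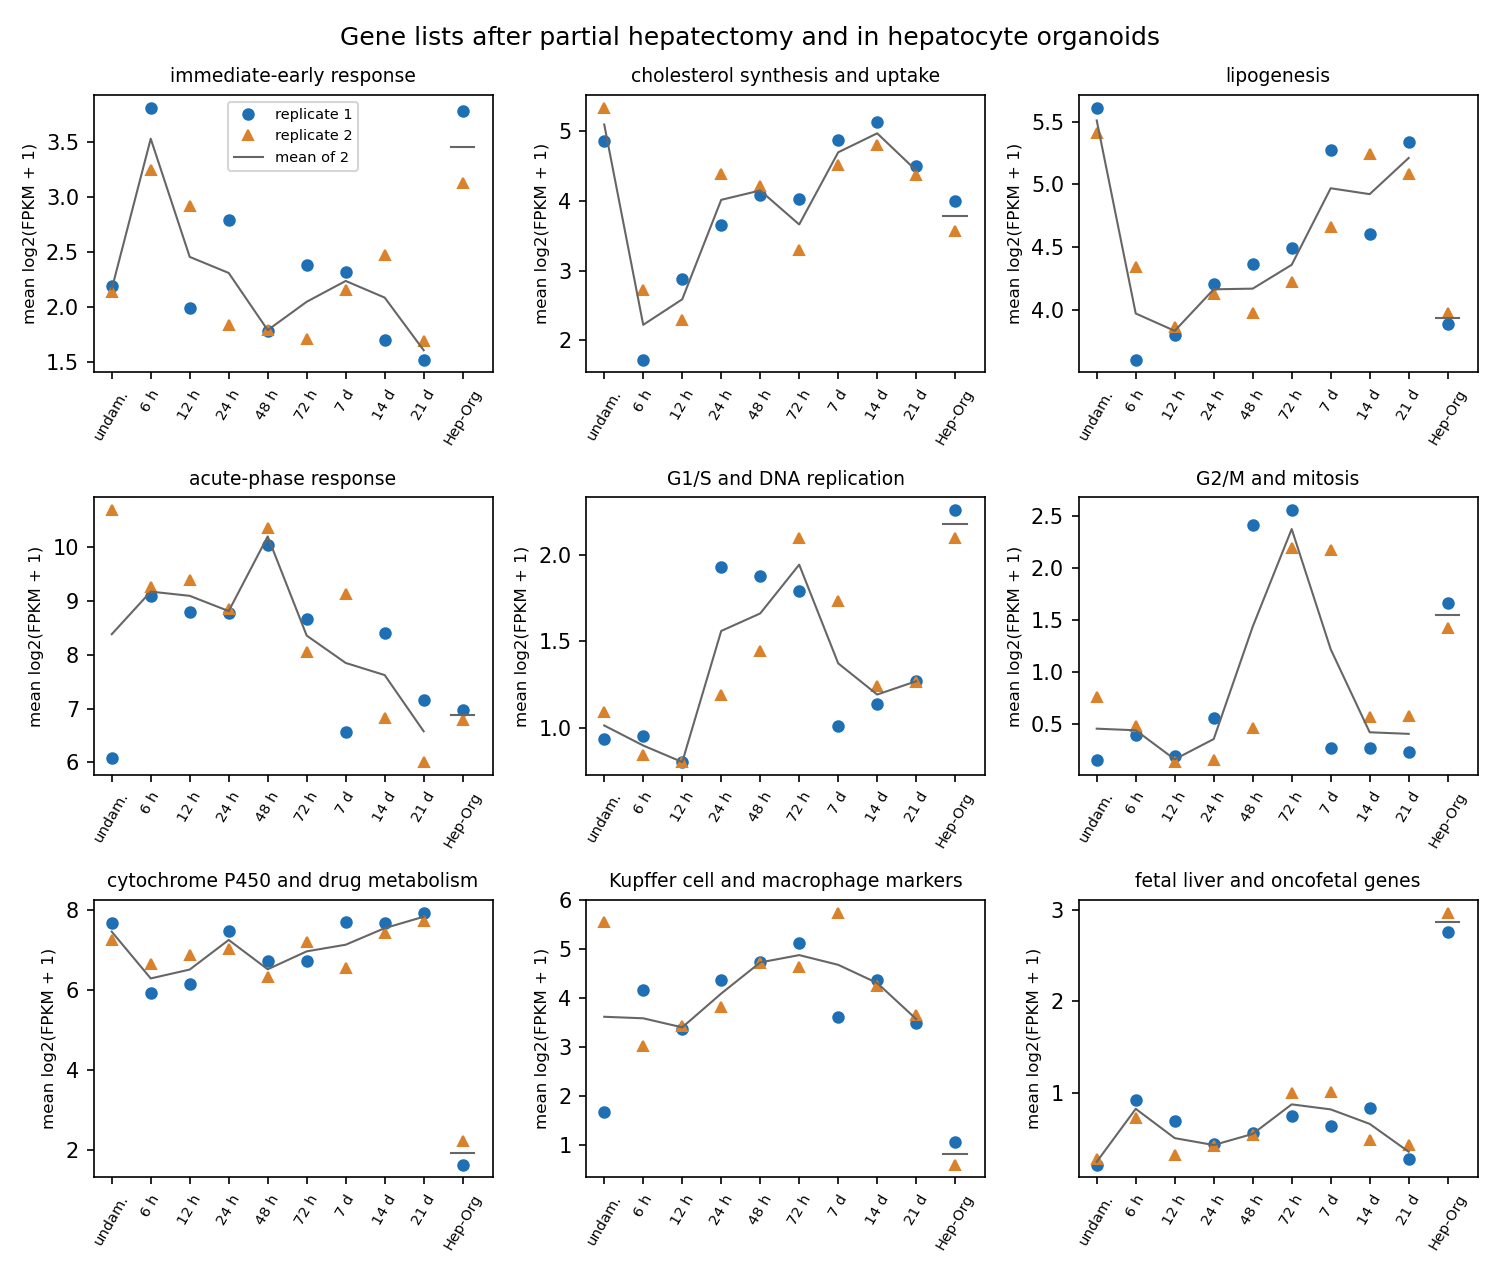
Mean log2(FPKM + 1) of the members of selected gene lists in each library, with groups along the horizontal axis, circles and triangles for replicates 1 and 2 and a grey line through the mean of both. The mitotic list was highest at 72 h (median difference 1.93 from undamaged liver) and cholesterol synthesis lowest at 6 and 12 h (-2.95 and -2.74).

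At 7 d the sex-biased genes made up the largest differences, and the libraries still carried the Xist pattern. Sult2a2 was at 646 ± 134 FPKM (log2 9.22, SE 0.948, limma adjusted p = 6.73e-04), Cyp2b9 at 640 ± 697 (7.83), and Sult2a1, a steroid sulfotransferase listed at 0 in undamaged liver, at 187 ± 31.3. Mup7 (log2 -11.51), Mup14 (-7.72) and Cyp4a12a (ENSMUSG00000066071, log2 -6.84, SE 0.780, limma adjusted p = 0.00164), a male-biased fatty acid hydroxylase, were the largest decreases. Of 10 female-biased genes 9 were higher, 10 adjusted over the list alone (median 6.71, camera adjusted p = 6.10e-36, 1.21e-04 at an estimated correlation). Of 12 male-biased genes 5 were lower, 12 adjusted over the list alone (median -4.62, camera adjusted p = 1.25e-23, 6.00e-04 at an estimated correlation). The ectonucleotidase Nt5e, a YAP/TEAD target, rose from 0.393 ± 0.123 to 10.3 ± 6.46 (log2 2.99, SE 0.448, limma adjusted p = 0.0104). Stellate markers rose with 0 of 17 called and 5 adjusted over the list alone (median 0.80, camera adjusted p = 1.95e-10, 0.176 at an estimated correlation). Mitotic genes (median 0.76, camera adjusted p = 2.96e-07, 0.591 at an estimated correlation) and replication genes (0.38, camera adjusted p = 8.00e-05, 0.579 at an estimated correlation) rose as lists with 0 members called, 0 adjusted over the list alone. Bub1 was at 0.192 and 4.26 in the libraries of 7 d. Kupffer cell (median 0.99, camera adjusted p = 0.00192, 0.603 at an estimated correlation), endothelial (0.69, camera adjusted p = 5.23e-04, 0.591 at an estimated correlation) and lymphocyte markers (1.08, camera adjusted p = 0.00273, 0.579 at an estimated correlation) rose with 0 called, 0 adjusted over the list alone. These calls ended or reversed without undamaged replicate 1 (-0.83, -0.30 and 0.68), and those of Kupffer cells and lymphocytes ended without 7 d replicate 2 (0.11 and 0.44). Heat shock genes fell as a list with 0 of 11 called, 0 adjusted over the list alone (median -0.71, camera adjusted p = 0.00365, 0.579 at an estimated correlation). This median was 0.09 after rescaling to the same sum. Limma called 31 genes higher and 25 lower, voom 7 and 5, and 43 and 12 were called after rescaling to the same sum. PHx 7 d versus undamaged called 33 genes without 7 d replicate 2, which also ended the calls of the mitotic (median -0.15) and replication (0.01) lists. The call of Mup14 ended without undamaged replicate 2 or 7 d replicate 2 (log2 -7.12 to -6.23). Of 139 genes called at 48 h, 72 h or 7 d, 31 were called at all 3 times in the same direction, 13 higher and 18 lower, and 18 of the 139 were on the 2 sex-biased lists.

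At 14 and 21 d no single gene passed the test against undamaged liver. Stellate markers rose as a list at 14 d with 0 of 17 called and 5 adjusted over the list alone (median 0.96, camera adjusted p = 1.01e-12, 0.395 at an estimated correlation). Lum was at 8.41 ± 3.17 FPKM against 0.803 ± 0.882 and the collagen Col3a1 at 2.52 ± 0.513 against 0.414 ± 0.501. Kupffer cell markers rose at 14 d (0 of 15 called, 0 adjusted over the list alone, median 0.70, camera adjusted p = 0.0462, 0.908 at an estimated correlation), a call that ended without any 1 of 13 libraries (-1.22 to 0.83) and reversed without undamaged replicate 1. Stellate markers rose at 21 d (0 of 17 called, 0 adjusted over the list alone, median 0.53, camera adjusted p = 7.83e-06, 0.789 at an estimated correlation), with a median of 0.34 without undamaged replicate 1, where the call ended. Mitochondrially encoded mRNAs fell as a list at 14 d (13 of 13 negative, median -1.73, camera adjusted p = 5.73e-04, 0.908 at an estimated correlation). None was called, 0 adjusted over the list alone, and mt-Nd5 was at 1835 ± 110 against 7651 ± 3370. At 21 d acute-phase genes fell as a list (27 of 27 negative, 0 called, 0 adjusted over the list alone, median -1.62, camera adjusted p = 3.15e-06, 0.789 at an estimated correlation). Crp was at 124 ± 27.3 against 723 ± 787. Fatty acid oxidation genes rose at 21 d (0 of 24 called, 0 adjusted over the list alone, median 0.73, camera adjusted p = 1.27e-04, 0.789 at an estimated correlation). Cholesterol synthesis fell (0 of 24 called, 0 adjusted over the list alone, median -0.67, camera adjusted p = 1.73e-04, 0.789 at an estimated correlation). The sex-biased lists did not pass the test at 14 d (male-biased median -0.57, camera adjusted p = 0.0668) or 21 d (0.01, camera adjusted p = 0.898). Limma called 0 of 13162 genes at either time, with 1014 and 1000 at an unadjusted p under 0.05, and voom called 0. PHx 14 d versus undamaged called 2 genes without undamaged replicate 1 or without any 1 library of 6 h or 24 h and 1 without 14 d replicate 1, and PHx 21 d versus undamaged 4 without undamaged replicate 1 and 2 without either 24 h library. The acute-phase call at 21 d ended without undamaged replicate 2 (median 0.26), and the fatty acid oxidation call without undamaged replicate 2 (0.16) or 21 d replicate 1 (0.37).

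The second question was how organoids differed from undamaged liver. Hep-Org had far lower levels of the genes of differentiated hepatocytes and higher levels of cholangiocyte and progenitor, fetal and p53 target genes, and 3 chemokines were among its 10 largest increases. Cyp2e1 (chromosome 7, 140763739 to 140774987), a xenobiotic-metabolising P450 of pericentral hepatocytes, fell from 2253 ± 19.9 to 0.0956 ± 0.135 FPKM (log2 -11.01, SE 0.731, limma adjusted p = 6.40e-07), and the apolipoprotein Apoa2 (chromosome 1, 171225054 to 171226379) from 13507 ± 4263 to 4.89 ± 0.642 (log2 -11.13, SE 0.794, limma adjusted p = 1.06e-06). The other largest decreases were in Mup7 (log2 -13.24), Mup12 (-13.09), Mup17 (-11.36), Mup3 (-11.24), Mup15 (-11.03), the serpins Serpina3k (-11.25) and Serpina1e (-10.29), and Mup22, listed at 0 in both Hep-Org libraries and at 2824 ± 3584 in undamaged liver. The chemokine Ccl20 (chromosome 1, 83116766 to 83119167) rose from 0.0647 ± 0.0915 to 341 ± 160 (log2 8.25, SE 0.310, limma adjusted p = 2.20e-08), Ccl2 from 1.62 ± 2.05 to 291 ± 58.8 (log2 7.05), and Cxcl5, listed at 0 in undamaged liver, was at 474 ± 354 (limma adjusted p = 1.72e-07). Sprr1a (chromosome 3, 92483952 to 92485895), a squamous epithelial envelope protein, rose from 0.114 ± 0.161 to 456 ± 62.6 (log2 8.68, SE 0.755, limma adjusted p = 5.38e-06) and Spp1, osteopontin (chromosome 5, 104435118 to 104441050), from 170 ± 231 to 3555 ± 1217 (log2 6.11, SE 1.41, limma adjusted p = 0.00603). Carboxypeptidase E, Cpe (log2 8.24), the tetraspanin Tspan8 (6.55), Ier3 (6.22), the intestinal cadherin Cdh17 (5.98) and Phgdh of serine synthesis (5.86) completed the 10 largest increases. Limma called 1352 genes higher and 1743 lower of 13162, and after rescaling each library to the same sum Hep-Org versus undamaged called 7700 higher and 813 lower. It called 1846 genes without Hep-Org replicate 1 and 2056 without replicate 2. The calls of Mup15 (log2 -11.04 to -8.04) and Mup17 (-11.37 to -10.50) each ended without any 1 of 3 libraries, and that of Spp1 without Hep-Org replicate 1 (5.76).

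Metabolic lists of the hepatocyte fell together in Hep-Org. All 28 urea cycle and amino acid catabolism genes were lower, also adjusted over the list alone (median -5.01, camera adjusted p = 4.52e-19, 0.0751 at an estimated correlation). Carbamoyl phosphate synthetase, Cps1 (chromosome 1, 67123026 to 67231259), was at 0.106 ± 0.00467 against 824 ± 380 (log2 -9.46, SE 0.765, limma adjusted p = 3.22e-06) and the tyrosine aminotransferase Tat at log2 -8.44. Of 32 P450 and drug metabolism genes 27 were lower, 27 adjusted over the list alone (median -5.37, camera adjusted p = 8.48e-18, 0.0327 at an estimated correlation). They included Ces3a (log2 -10.25), Cyp2f2 (-9.75) and Cyp2j5 (-8.27). Of 30 hepatocyte identity genes 26 were lower, 27 adjusted over the list alone (median -4.35, camera adjusted p = 1.99e-15, 0.0354 at an estimated correlation). Of 22 bile acid genes 16 were lower and 1 higher, 18 and 1 adjusted over the list alone (median -4.20, camera adjusted p = 3.01e-10, 0.0354 at an estimated correlation). They included the bile acid CoA ligase Slc27a5 (log2 -8.25) and the carriers Slc10a1 (-7.99) and Slco1b2 (-7.71). Of 14 gluconeogenesis genes 11 were lower, 12 adjusted over the list alone (median -3.05, camera adjusted p = 1.14e-06, 0.0751 at an estimated correlation). Of 15 widely expressed glycolysis genes 8 were higher, 8 adjusted over the list alone (median 1.21, camera adjusted p = 3.68e-04, 0.0354 at an estimated correlation). Pyruvate kinase M, Pkm (chromosome 9, 59656368 to 59679375), was at 144 ± 67.9 against 5.50 ± 6.98 (log2 5.02, SE 0.739, limma adjusted p = 3.25e-04). Fatty acid oxidation had 14 of 24 lower, 16 adjusted over the list alone (median -1.72, camera adjusted p = 1.25e-05, 0.342 at an estimated correlation). Lipogenesis had 8 of 16 lower and 1 higher, also adjusted over the list alone (median -1.46, camera adjusted p = 0.00745, 0.313 at an estimated correlation). Cholesterol synthesis had 9 of 24 lower, 10 adjusted over the list alone (median -1.34, camera adjusted p = 6.33e-04, 0.433 at an estimated correlation). The medians of these 3 lists turned positive after rescaling to the same sum (0.05, 0.42 and 0.49). Of 16 periportal genes 12 were lower, 13 adjusted over the list alone (median -5.45, camera adjusted p = 1.00e-08, 0.0751 at an estimated correlation). Of 17 pericentral genes 10 were lower and 1 higher, 12 and 1 adjusted over the list alone (median -2.24, camera adjusted p = 1.20e-06, 0.142 at an estimated correlation).

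Lists of immature, biliary and proliferating cells rose in Hep-Org. Of 10 fetal liver and oncofetal genes 7 were higher, 7 adjusted over the list alone (median 3.08, camera adjusted p = 8.76e-05, 0.0313 at an estimated correlation). The transcription factor Sox4 was at 14.6 ± 0.636 FPKM against 0.0485 ± 0.0398 and Cd24a at 60.2 ± 7.33 against 0.482 ± 0.628. Of 15 cholangiocyte and progenitor markers 10 were higher, 10 higher and 1 lower adjusted over the list alone (median 2.17, camera adjusted p = 3.76e-07, 0.0313 at an estimated correlation). The biliary keratin Krt19 (chromosome 11, 100140810 to 100148665) was at 13.5 ± 5.29 against 0.0526 ± 0.0744 (log2 3.74, SE 0.467, limma adjusted p = 9.00e-05) and Muc1 at log2 2.82. Of 18 YAP/TEAD targets 6 were higher, 7 adjusted over the list alone (median 1.13, camera adjusted p = 1.09e-04, 0.0313 at an estimated correlation). Ankrd1 was listed at 0 in undamaged liver and was at 9.12 ± 2.07 in Hep-Org. Of 15 p53 targets 11 were higher, 12 adjusted over the list alone (median 2.23, camera adjusted p = 8.08e-08, 0.0313 at an estimated correlation). Ccng1 was at 65.8 ± 14.7 against 7.34 ± 0.0242 and Phlda3, an inhibitor of AKT, at 52.7 ± 23.9 against 0.163 ± 0.186. Of 31 replication genes 16 were higher and 1 lower, 17 and 1 adjusted over the list alone (median 1.14, camera adjusted p = 8.44e-07, 0.313 at an estimated correlation). Cyclin D1, Ccnd1 (chromosome 7, 144929931 to 144939925), was at 72.1 ± 15.5 against 3.06 ± 2.46 (log2 4.30, SE 0.609, limma adjusted p = 2.39e-04). Mitotic genes rose as a list with 1 of 35 called, 0 adjusted over the list alone (median 1.02, camera adjusted p = 3.16e-04, 0.579 at an estimated correlation). The proliferation marker Mki67 was at 4.08 ± 0.873 against 0.579 ± 0.627. Immediate-early genes had 8 of 22 higher, 8 adjusted over the list alone (median 1.26, camera adjusted p = 4.97e-04, 0.313 at an estimated correlation). Myc was at 14.5 ± 2.0 against 1.45 ± 0.000188. Ribosome biogenesis had 9 of 23 higher, 9 adjusted over the list alone (median 0.85, camera adjusted p = 3.15e-06, 0.307 at an estimated correlation).

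Markers of the other liver cells, and several signalling groups, were lower or not different in Hep-Org. Endothelial markers had 12 of 15 lower, 14 adjusted over the list alone (median -2.45, camera adjusted p = 1.20e-06, 0.313 at an estimated correlation). Kupffer cell markers had 7 of 15, 10 adjusted over the list alone (median -2.91, camera adjusted p = 6.75e-04, 0.433 at an estimated correlation). Clec4f was at 0.00397 ± 0.00562 FPKM against 95.9 ± 123. The stellate list did not pass the test (1 of 17 higher and 2 lower, also adjusted over the list alone, median -0.29, camera adjusted p = 0.151), nor did lymphocyte (0 of 7, median -0.50, camera adjusted p = 0.368) or neutrophil markers (0 of 11, median -1.07, camera adjusted p = 0.232). Of 6 erythroid markers Alas2 was lower (median -1.19, camera adjusted p = 0.159), and the 4 measured mesothelial markers, too few for a test, had a median of 0.03. Acute-phase genes had 8 of 27 lower, 8 adjusted over the list alone (median -1.92, camera adjusted p = 0.0155, 0.627 at an estimated correlation). Interferon response genes had 6 of 15, 6 adjusted over the list alone (median -1.03, camera adjusted p = 0.00206, 0.342 at an estimated correlation). The unfolded protein response had 8 of 16 lower and 2 higher, 10 and 2 adjusted over the list alone (median -1.90, camera adjusted p = 0.0137, 0.433 at an estimated correlation). Mitochondrially encoded mRNAs had 7 of 13 lower, 8 adjusted over the list alone (median -3.28, camera adjusted p = 6.75e-04, 0.433 at an estimated correlation). Growth factors and receptors went both ways, 5 of 19 higher and 8 lower, also adjusted over the list alone (median -0.90, camera adjusted p = 0.216, past the threshold without Hep-Org replicate 1 at -1.23), with Igf1, made by hepatocytes, at 0.0659 ± 0.00496 against 100 ± 32.5. Circadian genes (0 of 17 called, 0 adjusted over the list alone, median -0.36, camera adjusted p = 0.601) and heat shock genes (0 of 11, 0 adjusted over the list alone, median -0.21, camera adjusted p = 0.637) did not pass the test. Male-biased genes were lower, 9 of 12 and 10 adjusted over the list alone (median -6.46, camera adjusted p = 3.76e-07, 0.0313 at an estimated correlation). Female-biased genes had 0 of 10 called with a median of 0.00 while the test pointed up (camera adjusted p = 0.810). The acute-phase (median 0.23) and interferon (-0.66) calls ended without undamaged replicate 2, and that of the unfolded protein response without undamaged replicate 2 (-0.76) or Hep-Org replicate 2 (-1.78). After rescaling to the same sum the 3 medians were 0.03, 0.26 and 0.02.

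**Figure D4:**
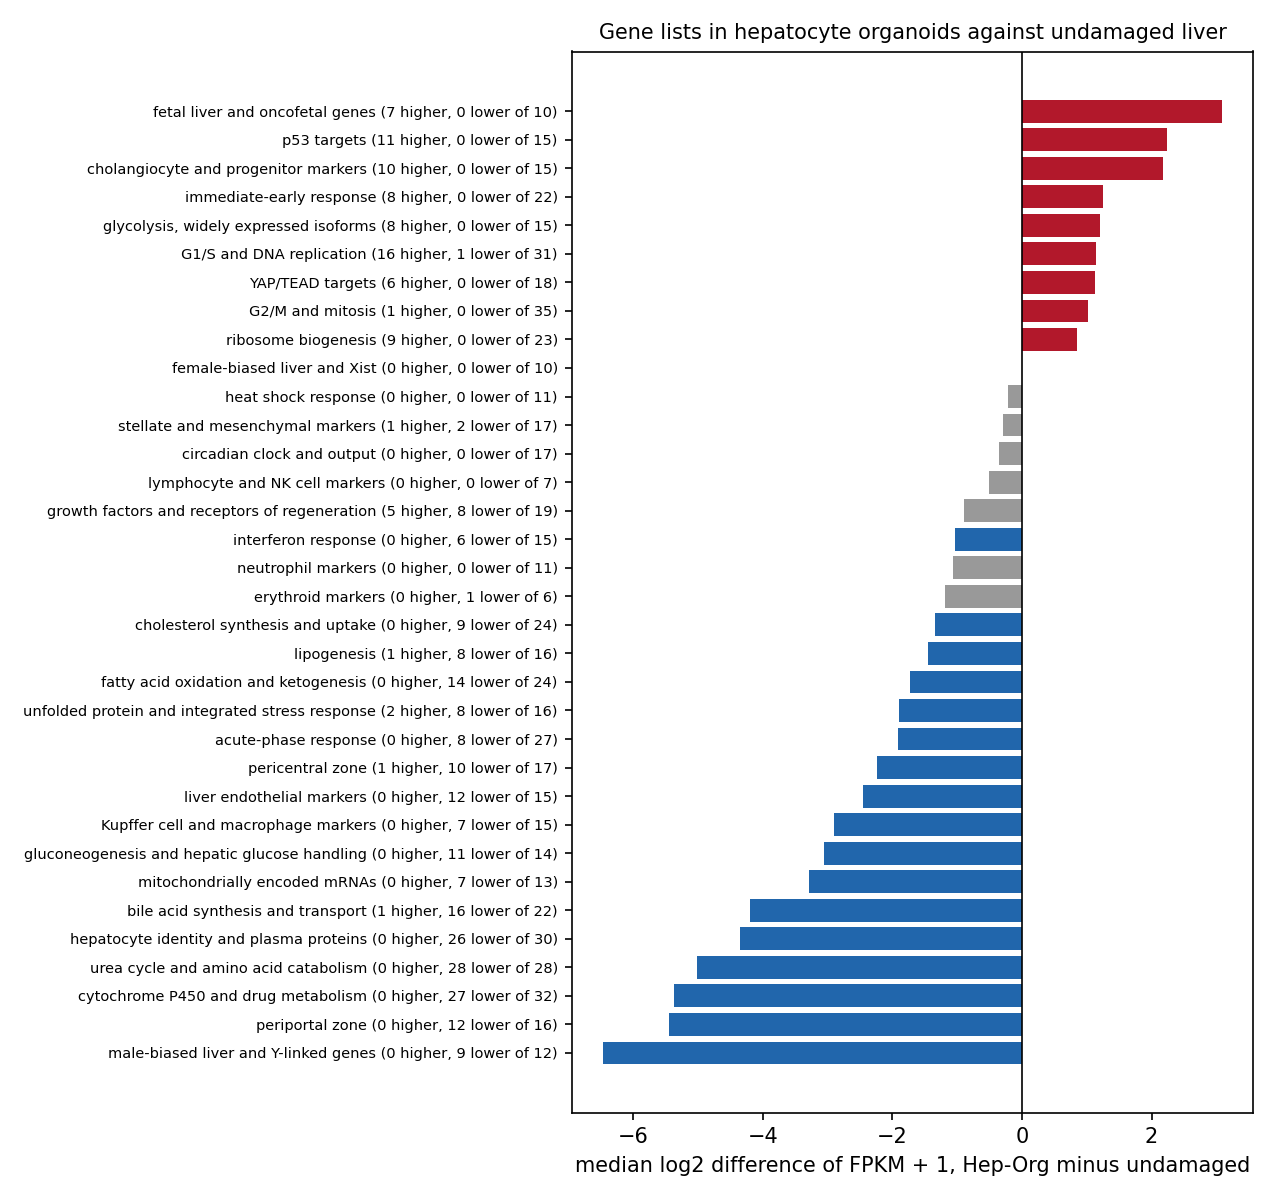
Median log2 difference of each gene list between Hep-Org and undamaged liver, with the numbers of members called higher and lower beside each name. Medians ran from -6.46 for male-biased genes to 3.08 for fetal liver and oncofetal genes.

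The third question was how organoids compared with regenerating liver in the window of the hepatocyte cell cycle, 24 to 72 h, and in that of late regrowth, 7 to 21 d. In both windows Hep-Org had lower levels of urea cycle and P450 genes and higher levels of Cxcl5 (log2 8.47 and 8.59), Ccl20 (8.14 and 8.24) and Sprr1a (8.04 and 8.55). The largest decreases were in Apoa2 (-10.14), Cyp2e1 (-10.08) and Serpina3k (-9.81) against 24 to 72 h, and in Cyp2e1 (-11.14), Apoa2 (-10.27) and Mup22, listed at 0 in Hep-Org, against 7 to 21 d. Ccnd1 was higher than at 24 to 72 h (72.1 ± 15.5 FPKM, n = 2, against 7.62 ± 4.63, n = 6, log2 3.25, SE 0.520, limma adjusted p = 4.77e-04). Replication genes were higher as a list, with 5 of 31 higher and 1 lower against 24 to 72 h, also adjusted over the list alone (median 0.37, camera adjusted p = 0.0364, 0.617 at an estimated correlation). Against 7 to 21 d, 11 were higher and 2 lower, 12 and 2 adjusted over the list alone (0.81, camera adjusted p = 8.90e-05, 0.370 at an estimated correlation). Mitotic genes did not pass the test against 24 to 72 h (0 of 35, median 0.19, camera adjusted p = 0.615). They were higher as a list against 7 to 21 d (1 of 35, 0 adjusted over the list alone, 0.79, camera adjusted p = 0.00326, 0.620 at an estimated correlation). The topoisomerase Top2a was at 4.34 ± 1.19 in Hep-Org, 3.73 ± 3.39 at 24 to 72 h and 1.09 ± 1.75 at 7 to 21 d. P53 targets were higher in both windows, 12 of 15 in each, 12 adjusted over the list alone (median 2.21, camera adjusted p = 1.18e-07, 0.0323 at an estimated correlation, and 2.41, camera adjusted p = 3.10e-08, 0.0379 at an estimated correlation). Fetal genes had 7 of 10 higher in each, 7 adjusted over the list alone (2.51, camera adjusted p = 0.00191, 0.0399 at an estimated correlation, and 2.59, camera adjusted p = 0.00123, 0.0379 at an estimated correlation). Cholangiocyte markers had 10 and 11 of 15, 10 and 11 adjusted over the list alone (2.12, camera adjusted p = 1.11e-07, 0.0323 at an estimated correlation, and 2.14, camera adjusted p = 7.99e-08, 0.0379 at an estimated correlation). Urea cycle genes were lower in 27 and 28 of 28, 28 and 28 adjusted over the list alone (-4.81, camera adjusted p = 1.76e-19, 0.0750 at an estimated correlation, and -5.14, camera adjusted p = 2.34e-20, 0.0678 at an estimated correlation). P450 genes were lower in 29 and 28 of 32, 30 and 29 adjusted over the list alone (-5.25, camera adjusted p = 7.00e-18, 0.0323 at an estimated correlation, and -5.66, camera adjusted p = 6.87e-19, 0.0379 at an estimated correlation). Lipogenesis and cholesterol synthesis did not pass the test against 24 to 72 h (medians -0.31 and -0.07, camera adjusted p = 0.643 and 0.732). Limma called 1342 genes higher and 1755 lower against 24 to 72 h, and 1477 and 1796 against 7 to 21 d. After rescaling to the same sum these were 7169 and 1151, and 6243 and 1321. Without Hep-Org replicate 1, Hep-Org versus PHx 24 to 72 h called 1881 genes and Hep-Org versus PHx 7 to 21 d 2143. The replication call against 24 to 72 h ended without 48 h replicate 2 (median 0.29) or 72 h replicate 1 (0.32), the fetal calls without Hep-Org replicate 2 (0.47 and 0.74), and the mitotic call against 7 to 21 d without 7 d replicate 1 (0.37).

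Of the liver groups, 24 h after PHx lay nearest to Hep-Org across genes. Spearman's rho of log2(FPKM + 1) between Hep-Org and liver libraries had a median of 0.666 at 24 h (0.655 to 0.675 over 4 pairs) and 0.630 for undamaged liver (0.620 to 0.645), with the lowest median, 0.608, at 6 h. Genes are not independent replicates, so no p-value is given. The 2 Hep-Org libraries had a rho of 0.958 with each other and the undamaged libraries one of 0.868. The number of genes limma called between Hep-Org and a single time was lowest at 48 h (2670) and was 2837 at 24 h and 3101 at 6 h.

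The last question was whether genes that changed early after PHx also differed in Hep-Org. Of the genes lower at 6 h, such as Slco1b2 and Cyp2f2, 513 were also lower in Hep-Org, where 110 were expected of independent sets of these sizes. Of those higher at 6 h, such as Myc and Nop58, 97 were also higher (62.5 expected), and 35 went opposite ways. At 12 h, 203 were lower in both (37.5 expected) and 19 higher in both (12.6 expected). At 48 h, 72 h and 7 d, 34, 50 and 23 were lower in both (4.63, 9.14 and 3.31 expected) and 0, 9 and 1 higher in both (1.95, 4.93 and 3.18 expected), among genes that include the sex-biased ones. Over all genes, Pearson's r between the Hep-Org and 6 h differences was 0.418, against 0.492 in simulated unchanged groups with the same undamaged libraries (20 draws). The covariance was 0.572 against a simulated 0.0973, a difference of 0.475. Each comparison used the same 2 undamaged libraries, which could not be divided into sets of 2, so part of the excess may come from them. Counted once over the 8 times, the overlap of Hep-Org and PHx changes in the same direction was 665 genes, and 345 without 6 h replicate 1.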

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

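The test of Y-linked genes, the tests of undamaged replicate 2, the test of 7 d replicate 2 as a library of 72 h, and the pairs of times set against each other for 4 gene lists were chosen after the results were seen. So were the comparisons with 7 d or 21 d as the reference, the setting apart of 14 d and the leaving out of acute-phase genes in the tests of undamaged replicate 2, the demand that the interval of the exchange test pass its bound, and the comparison of the 2 libraries list by list. Under the bound of 0.01 set before, which had no interval, the exchange was excluded (-0.0108).

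In 4 gene lists the test pointed up at 1 time and down at another. Those times were compared with camera, adjusted over the 4. Lists and times were picked for opposite signs, which the p-values partly restate. With an estimated correlation none passed (adjusted p = 0.0694 for the first 3, 0.176 for the last). The first 3 pairs differed in the Xist pattern and so perhaps sex. Acute-phase genes were higher at 48 h than at 21 d by a difference of medians of 2.97 (1.35 and -1.62 against undamaged liver, camera adjusted p = 1.99e-17, 2.40 to 3.57 on leaving out each library). Ribosome biogenesis factors were higher at 6 h than at 7 d by 1.32 (0.87 and -0.44, camera adjusted p = 9.94e-13, 0.997 to 1.82), and the 7 d call ended without 7 d replicate 1 (-0.29). Interferon response genes were higher at 7 d than at 12 h by 1.21 (0.58 and -0.62, camera adjusted p = 9.20e-08), and by 0.77 without 12 h replicate 1 to 1.52 without 12 h replicate 2. Against undamaged liver their 7 d call ended without undamaged replicate 1 (0.05), and their 12 h call without undamaged replicate 2 (-0.24) or 12 h replicate 1 (-0.20). Mitochondrially encoded mRNAs were higher at 6 h than at 14 d by 3.11 (1.38 and -1.73, camera adjusted p = 3.23e-06, 2.11 to 4.13), with 40.7% mitochondrial reads in 6 h replicate 2.

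Sex-biased liver genes moved at 48 h, 72 h and 7 d together with Xist. A turn of male animals towards the female pattern would have left Y-linked transcripts in place, but the highest value of 4 Y-linked genes in those 6 libraries was 0 FPKM, where every other PHx library reached at least 9.66, so this is excluded. Female animals at these 3 times remain a candidate explanation: 3 of 4 X-linked genes that escape inactivation were higher in the 6 libraries than in the other 10 (median log2 0.41; Kdm6a 0.42, Eif2s3x 0.77, Ddx3x 0.40 and Kdm5c -0.09), and Xist was at 13.6 to 23.7 FPKM against at most 0.137. Sex was then confounded with these 3 times for every gene, sex-biased or not. No difference between them and undamaged liver or other PHx times can be assigned to regeneration apart from sex. With 7 d as the reference, which shares the pattern, limma called 1 gene at 48 h and 1 at 72 h (467 and 318 at an unadjusted p under 0.05), while female-biased genes as a list were lower at 48 h than at 7 d (median -1.48, 0 of 10 called, 4 adjusted over the list alone, camera adjusted p = 2.51e-08, 0.0399 at an estimated correlation).

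Undamaged replicate 2 had acute-phase genes (27 of 27, median log2 3.66) and Kupffer cell transcripts far above replicate 1. Its cholesterol or male-biased list mean lay outside each PHx range but that of 14 d, by log2 0.640 at the nearest, 24 h. Such a range, of 2 libraries widened by their gap, cannot exclude a time. A library of 14 d and an undamaged one cannot be told apart by these lists (-0.00689, inside that range), and its rho was 0.905 with 14 d replicate 2 against 0.868 with undamaged replicate 1. Kupffer cell markers rose by 2.31 more than endothelial ones (log2 4.18 and 1.86, 95% interval over genes 1.29 to 2.86). With 1 library each this cannot exclude a lower share of hepatocytes. More Kupffer cells, an inflamed animal or a response to cell isolation stay open as untested.

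Cell-cycle genes were low in 48 h replicate 2 and high in 7 d replicate 2 (Mki67 at 8.09 and 0.616 FPKM in the replicates of 48 h, 0.224 and 4.91 in those of 7 d). The values on an exchange of the 2 libraries were split: over 13096 genes outside the cell-cycle lists, the rho of 48 h replicate 2 with 7 d replicate 1 minus its rho with 48 h replicate 1 was -0.0108 (95% interval -0.0159 to -0.00608, 1000 bootstrap draws over genes). In favour, 7 d replicate 2 was nearer to 48 h replicate 1 by 0.0119 (0.00715 to 0.0168), while the acute-phase means (10.04 and 10.36 at 48 h, 6.56 and 9.14 at 7 d) would lie further apart within both times after an exchange. Of the 32 lists outside the cell cycle, 48 h replicate 2 was nearer to its own label in 12 and to 7 d replicate 1 in 3 beyond the bootstrap interval, and 7 d replicate 2 nearer to its own in 3 and to 48 h replicate 1 in 7. An exchange, a library of 72 h under the 7 d label and animals that differed in the pace of regrowth, which had no test, cannot be told apart: the interval of -0.0108 spans the bound of -0.01, and the rho of 7 d replicate 2 with the 72 h libraries (0.926 and 0.938) lay on both sides of the 0.932 between these and above its 0.897 with 7 d replicate 1.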

How the results depend on the processing

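Voom on recovered reads, 21 d or 7 d as the reference and leaving out the times of 48 h, 72 h and 7 d were chosen after the data were seen, and all other alternatives before. The limits were 2 libraries per group, undamaged liver in 1 submission alone and depths of 13.7 to 41.4 M reads (M, 1000000). The values as reported were 1436 genes for PHx 6 h versus undamaged, 406 for PHx 12 h versus undamaged, 0 for PHx 24 h versus undamaged, 54 for PHx 48 h versus undamaged, 117 for PHx 72 h versus undamaged, 56 for PHx 7 d versus undamaged, 0 for PHx 14 d versus undamaged and 0 for PHx 21 d versus undamaged. Hep-Org versus undamaged called 3095, Hep-Org versus PHx 24 to 72 h 3097, Hep-Org versus PHx 7 to 21 d 3273 and the PHx time course 1252. The gene lists had 188 comparisons past the threshold, the Hep-Org similarity to liver groups was 0.666 at its highest and the overlap of Hep-Org and PHx changes was 665. With no replicate block the counts were 732 at 12 h, 30 at 24 h, 91 at 48 h and 425 at 72 h, and with a replicate block by number 5 at 24 h and 229 at 72 h. The first submission only, with 1 library per PHx time and so fewer samples, called 13 at 6 h, 1 at 12 h, 11 at 48 h, 18 at 72 h, 18 at 7 d and 5 over time, with a similarity of 0.646 and an overlap of 8. With no filter on low values, and so more genes tested, the counts were 741 at 6 h, 125 at 12 h, 1 at 24 h, 17 at 48 h, 31 at 72 h, 26 at 7 d, 1 at 21 d and 543 over time, with a similarity of 0.793 and an overlap of 322. Rescaled to a sum of 1000000, they were 423 at 6 h, 79 at 12 h, 27 at 48 h, 8513, 8320 and 7564 for the 3 Hep-Org comparisons, 769 over time and 252 for the overlap, and this rescaling moves the median of all genes as given above. A pseudocount of 0.1 called 1 at 24 h, 61 at 72 h and 35 at 7 d. Voom called 12 at 48 h, 39 at 72 h and 12 at 7 d, with a similarity of 0.722. An estimated correlation left 29 of 188 list comparisons. With 21 d as the reference 12 h called 768, with 7 d as the reference 48 h and 72 h called 1 each, and without the times of 48 h, 72 h and 7 d 12 h called 239 and 24 h 1. Apart from the fewer samples, the added genes and the shift, the cause was not tested. The 15 comparisons were within 1.5 times their values under median-ratio rescaling, and 24 h lay nearest to Hep-Org in all settings tabled.

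Leaving out each library in turn assumed that a lone sample varies like the other groups. The ranges were 474 to 1824 for PHx 6 h versus undamaged (lowest without 6 h replicate 1), 95 to 484 for PHx 12 h versus undamaged (95 and 244 without 12 h replicates 1 and 2, 270 without 72 h replicate 1 or Hep-Org replicate 2) and 0 to 23 for PHx 24 h versus undamaged (23 without 24 h replicate 2, 4 and 10 without 6 h replicates 1 and 2, 3 and 2 without undamaged replicates 1 and 2). They were 19 to 61 for PHx 48 h versus undamaged (22 without undamaged replicate 1, 33 and 19 without 48 h replicates 1 and 2, 35 without either 72 h library) and 17 to 283 for PHx 72 h versus undamaged (283 without undamaged replicate 1, 23 and 17 without 72 h replicates 1 and 2, 234 and 231 without 7 d replicates 1 and 2, 71 without any library of 14 d or 21 d, 66 without either Hep-Org library). PHx 7 d versus undamaged ran from 33 (without 7 d replicate 2) to 59, PHx 14 d versus undamaged from 0 to 2 (2 without undamaged replicate 1 or any library of 6 h or 24 h, 1 without 14 d replicate 1) and PHx 21 d versus undamaged from 0 to 4 (4 without undamaged replicate 1, 2 without either 24 h library). Hep-Org versus undamaged ran from 1846 to 3202 (1846 and 2056 without Hep-Org replicates 1 and 2), Hep-Org versus PHx 24 to 72 h from 1881 to 3205 and Hep-Org versus PHx 7 to 21 d from 2143 to 3367 (both lowest without Hep-Org replicate 1). The PHx time course ran from 741 to 1520 (741 without 6 h replicate 1, 783 without 21 d replicate 1), gene lists from 170 to 199, the Hep-Org similarity to liver groups from 0.658 to 0.691 (highest without Hep-Org replicate 1) and the overlap of Hep-Org and PHx changes from 345 (without 6 h replicate 1) to 782. Kupffer cell medians ran from -0.78 to 2.89 at 48 h, -0.83 to 2.97 at 7 d and -1.22 to 2.68 at 14 d, reversed without undamaged replicate 1 and highest without replicate 2. The acute-phase median at 14 d ran from -2.60 without undamaged replicate 1 to 0.91 without replicate 2, where it reversed. Of 62 calls of named genes 42 kept their side of the threshold without each library, as did 115 of 195 list results.

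Beside these counts the replicate block changed no other call, with 62 named genes on the same side without it or with a block by number, except 3 lists that lost their call: hepatocyte identity at 24 h (-0.54), interferon response at 72 h (0.41) and acute-phase genes at 14 d (-0.82). Of the 62 genes 54 kept their call with a pseudocount of 0.1, 50 after rescaling to a sum, 47 with no filter on low values, 42 in the first submission only and 41 with voom, and no gene reversed under these settings.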

Other observations

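Several genes of the circadian clock differed widely between the replicates of a time, and the genes given here were chosen after their values were seen. The clock output gene Dbp was at 20.6 and 0.128 FPKM in replicates 1 and 2 of 14 d and at 7.72 and 0.741 at 24 h. Arntl, which peaks in the opposite phase, was at 0.254 and 3.21 at 14 d and at 0.184 and 3.47 at 21 d, and Per3 at 2.43 and 0.140 at 14 d. The hour of collection is not given in the labels.

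The p53 target Cdkn1a, which restrains the cell cycle, was at 47.4 and 11.9 FPKM at 6 h and 21.8 and 50.8 at 12 h, against 7.47 and 10.1 in undamaged liver, and was at 28.1 and 41.4 in Hep-Org. The 2 organoid libraries differed in hepatocyte and fetal transcripts: Alb was at 3132 and 86.4, Afp at 3.17 and 33.6, H19 at 73.4 and 14.0 and Gpc3 at 1.55 and 29.3.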
